A study of Homo sapiens with 6 samples.

How the data were processed

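Gene expression was measured on 6 Affymetrix arrays, 3 of littoral cells and 3 of vascular endothelial cells of the human spleen. Cells had been freed from fresh tissue by enzymes, depleted of CD45-positive cells and red cells, and sorted by flow cytometry, and total RNA was amplified and labelled with biotin, per the labels. The groups and replicate numbers were taken from the sample titles, which call the replicates biological. The labels do not state whether samples with the same number came from 1 donor.

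The deposited values are log2 RMA signals per probe set, normalized by the authors, with RMA named per the file headers. The software, its version and whether the 6 arrays were normalized together are not given in the sources used here. The values were read from the series table, whose columns carry the sample labels; the design had named the annotated table as the source, but its 6 signal columns match no sample label and were not used. Gene symbols came from the annotated table, as deposited. The names of those 6 columns carry 2 batch stamps, 1 on 4 columns and the other on 2. The names do not tie the columns to samples, and their values were not compared with the series table, so a batch was not tested. Of the probe sets, 40783 had 1 gene symbol and were used, 4193 had several symbols, 9513 had none, 68 had a symbol turned into a date by a spreadsheet and 62 were controls. Another 56, of sex-specific genes, were left out. The brightest probe set by mean stood for each of 19858 genes. Of their symbols 17121 were current in the reference gene table of GRCh38.p14, used for names only, and 1412 were an older name of 1 gene there.

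The background limit of an array was the 95th percentile of 143 probe sets of olfactory receptors and keratin-associated proteins, which these cells were assumed not to express. It was 6.83, 6.67 and 7.45 on the littoral and 6.60, 6.60 and 7.92 on the vascular arrays. A gene at background on all arrays of 1 group was given a fold of the form at least N-fold, from the limit. RNA quality was read from the control probe sets. The 5' signal of ACTB was under the background limit of every array and that of GAPDH on some, so the values below cannot show equal RNA quality. The 3' signal of GAPDH exceeded the 5' signal by 2.44 ± 0.99 in littoral and 2.64 ± 0.79 in vascular cells on the log2 scale (SD, n = 3; exact two-sided permutation p = 0.7), and that of ACTB by 6.89 ± 0.14 and 5.75 ± 2.00 (SD, n = 3; exact two-sided permutation p = 0.6).

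Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with statmod 1.5.0, on all 6 arrays, without a block, and p was adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Before the data were examined, 31 gene lists with 618 distinct genes were fixed, 16 of which had no probe set of 1 symbol, while 11 were matched through older symbols. Each list was tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the lists. The rule for named genes was fixed at the same time. It took up to 15 genes in each direction with the largest differences among those past the threshold, without overlap between the groups and above background on all arrays of the higher group. It also took up to 3 members of each list in each direction, or the member with the smallest p where none passed, and the sort antigens, SIRPA and FHOD1. Genes of the sex chromosomes that tell the sexes apart were never named, and HLA, immunoglobulin and T cell receptor genes only as levels. The rule was applied again to the fit without both replicate 3 arrays, and genes named in the closing part outside it were chosen after their values were seen. Some genes that the rule takes are not reported here.

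Same-numbered arrays deviated together from their group means, with correlations over genes of 0.536, 0.701 and 0.737. These passed the limit of 0.1 fixed beforehand, so the fit with the number as a block is given beside results where it changed a call. The deviations follow the replicate 3 arrays of both groups, which differ from the rest in the same way. Arrays with different numbers passed that limit as well, at 0.654 for littoral replicate 2 and vascular replicate 1 and 0.440 for littoral replicate 1 and vascular replicate 2. The correlations therefore cannot show that the numbers pair the samples.

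Alternatives fixed beforehand were the replicate block, each array left out in turn, quantile normalization again, median centring, 2 filters on dim genes, other ways of treating several probe sets of a gene, an intensity trend with robust eBayes, an unequal-variance test per gene, treat against 1.5-fold and the other set tests. After the data were seen, fits without both replicate 3 arrays, with and without the block, with replicate 3 against the rest as a block, and with limma's array weights were added. Weights for each array did not converge, so 1 variance was fitted for both replicate 3 arrays and 1 for the other 4, giving weights of 0.130 and 2.77.

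The fits were tested on simulated data of 19858 genes with 200 changed. With 6 arrays, 0% of genes changed by 1 log2 unit, 11.9% of those changed by 2 and 56.1% of those changed by 4 were recovered, with 4 unchanged genes called; with 4 arrays these were 0%, 29.9% and 74.2%, with 2 unchanged genes called. Of 31 unchanged lists 0 were called by camera in either simulation, in which genes varied independently. A gene also had the same spread on every simulated array, whereas in the data the replicate 3 arrays differ from the rest. The rates simulated for 6 arrays may therefore not hold for these data.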

Results

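Splenic littoral cells, the endothelial cells that line the venous sinuses of the red pulp, were compared with vascular endothelial cells of the human spleen. Both populations had been sorted from fresh tissue on PECAM1 (CD31) and the absence of CD3 and CD45, littoral cells as CD34-negative and CD8A-positive and vascular cells as CD34-positive and CD8A-negative. RNA of 3 littoral and 3 vascular samples, described as biological replicates, was amplified and hybridised to 6 arrays, read here as log2 RMA signals for 19858 genes. The comparison asks how gene expression of littoral cells differs from that of other endothelium of the same organ.

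The sort antigens followed the gates on the replicate 1 and 2 arrays and less clearly on replicate 3. CD8A read 12.4, 12.6 and 8.78 on the littoral arrays and 4.41, 6.87 and 5.94 on the vascular arrays. CD34 read 6.57, 6.34 and 7.46 on littoral and 9.91, 9.57 and 7.78 on vascular arrays, so that the 2 replicate 3 arrays differed by -0.32. On vascular replicate 3 CD34 was under the background limit of 7.92, and on littoral replicate 3 it lay just above the limit of 7.45. PECAM1, by its brightest probe set, was bright on all arrays, at 12.49 ± 0.40 in littoral and 13.52 ± 0.43 in vascular cells (SD, n = 3 each). Its other probe sets were dimmer. Of these, 1 read 8.77 or more on every array and 1 was under the background limit of every array. Another read 5.77, 6.89 and 6.29 on the littoral arrays, and the last 5.39 on vascular replicate 3. CD3E averaged 5.70 ± 0.31 and 5.72 ± 0.07 and CD3G 4.39 ± 0.56 and 4.33 ± 0.45 (SD, n = 3), under the background limit of every array. CD3D read 6.78, 6.70 and 7.14 on littoral and 6.51, 6.37 and 7.97 on vascular arrays, above the limit on littoral replicate 2 and vascular replicate 3. PTPRC, which encodes CD45, averaged 6.02 ± 1.22 and 5.45 ± 0.73 (SD, n = 3), and was above the limit on littoral replicate 1 alone, at 7.40. No finding is drawn from these genes, which defined the samples.

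The replicate 3 arrays stood apart from the rest. Genes above the array's background limit made up 54.1%, 53.8% and 39.4% of those tested on the littoral arrays and 57.0%, 57.1% and 25.1% on the vascular arrays. Over all probe sets the vascular replicates 1 and 2 correlated at 0.982, against 0.679 for vascular replicates 1 and 3, and littoral replicates 1 and 2 at 0.974, against 0.874 for 1 and 3 (Pearson's r across probe sets, which are not independent). The 3' probe set of ACTB exceeded the 5' one by 7.02, 6.74 and 6.90 on the littoral and 6.93, 6.88 and 3.44 on the vascular arrays, and that of GAPDH by 3.15, 2.87 and 1.32 and by 3.05, 3.14 and 1.73. The 5' signal of ACTB lay under the background limit of every array, and that of GAPDH on littoral replicates 1 and 3 and vascular replicate 3. These differences are therefore limited by the floor. The 3.44 came with a 3' signal of 10.06, against 12.71 and 12.61 on vascular replicates 1 and 2. The first principal component, with 68.8% of the variance, parted replicate 3 from the others, and the second, with 18.9%, parted the cell types. The smallest p an exact test of 3 against 3 can give is 0.1, so that limma's moderated test was used across genes. The number of arrays limits the precision of every value, and counts are also given without both replicate 3 arrays, a choice made after the data were seen.

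**Figure D1:**
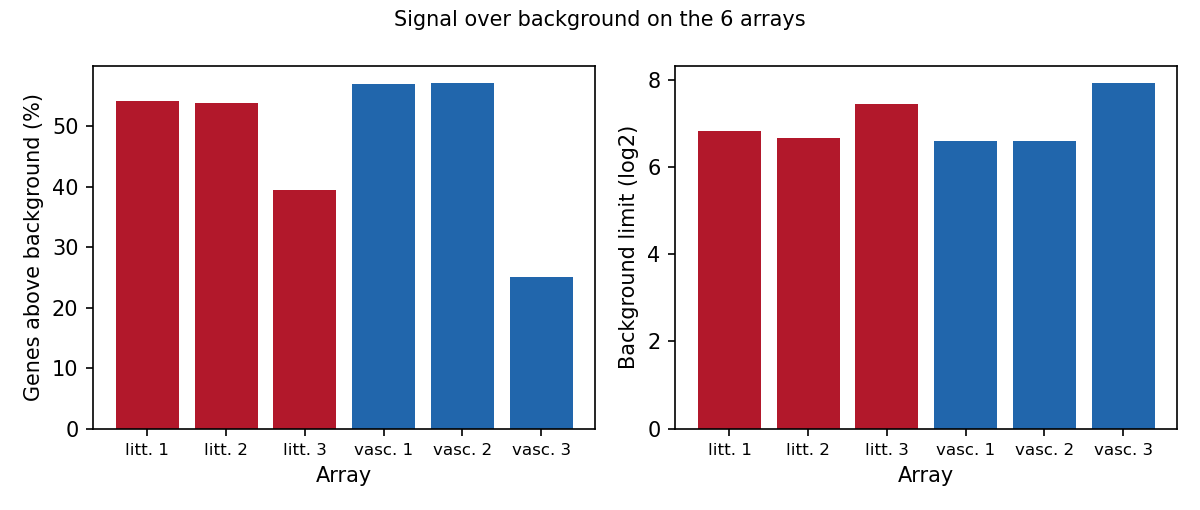
Percentage of genes above the background limit (left) and the limit itself in log2 units (right) on each array, littoral in red and vascular in blue, 1 bar per array. The vascular replicate 3 array has 25.1% of genes above its limit of 7.92.

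In all 6 arrays, littoral cells expressed 6 genes more strongly than vascular cells and 5 genes less strongly. The endocytic hyaluronan receptor STAB2 was at least 11.6-fold higher in littoral cells, at 10.57 ± 0.09 against 5.85 ± 0.64 (SD, n = 3; limma adjusted p = 0.037). The short-chain dehydrogenase DHRS2 was higher in littoral cells at 12.73 ± 0.23 against 5.45 ± 1.39 (SD, n = 3; adjusted p = 0.0462), and 1 of 3 vascular arrays, replicate 2, was above background. The other probe set of DHRS2 read 9.43, 9.41 and 8.25 on littoral and 7.21, 7.16 and 8.60 on vascular arrays, the other way on replicate 3. The ephrin receptor EPHA7 was at least 10.2-fold higher (fitted log2 difference 4.26, SE 0.32), BEX2 at least 9.06-fold (4.04, SE 0.28), KAZN 21.0-fold (4.39, SE 0.42; above background on 2 of 3 vascular arrays) and the actin-binding COTL1 11.1-fold (3.47, SE 0.33). On the vascular side stood SMAD6, an inhibitor of BMP signalling, at 11.30 ± 0.36 against 5.26 ± 0.18 in littoral cells (SD, n = 3; adjusted p = 0.00664), and the Notch target HEY1, 65.4-fold higher at 13.80 ± 0.24 against 7.77 ± 0.67 (adjusted p = 0.0169). The SMAD6 call rested on 1 probe set that may cross-hybridise, and without such probe sets the difference was 0.15, the other way (adjusted p = 1), from a probe set under the background limits. The endothelin receptor EDNRB was at least 27.9-fold higher in vascular cells, the lipid phosphatase PPAP2A (now PLPP1) 34.2-fold and the transcription factor SOX5 at least 5.32-fold. The calls of HEY1, EDNRB and COTL1 also rested on probe sets that may cross-hybridise, and without such probe sets 7 of the 11 genes passed. The other probe sets of EDNRB read 10.38 or more on vascular replicates 1 and 2, but 5.68 and 5.23 on replicate 3, under its background limit.

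These 11 genes differed at least 2-fold, and for each the 3 arrays of the groups did not overlap. Such separation alone was seen in 1951 genes, or 9.82%, where chance gives 10%, and 1140 genes had an unadjusted p under 0.05. Of the 10 genes with more than 1 probe set, 9 had all probe sets on the same side on the replicate 1 and 2 arrays and 4 on all arrays. On the replicate 1 and 2 arrays, SMAD6 passed 2-fold on 1 of its 4 probe sets and SOX5 on 2 of 4. The other probe set of HEY1 read 7.82 on vascular replicate 3. A further probe set of KAZN went the other way between the replicate 3 arrays, at 7.47 on littoral and 7.92 on vascular, and one of COTL1 read 4.40 on littoral replicate 3. With the replicate number as a block, 55 genes were called, 43 higher in littoral and 12 higher in vascular cells. The call count rested on single arrays: it was 0 without littoral replicate 1, littoral replicate 2 or vascular replicate 1 (726, 709 and 779 genes at an unadjusted p under 0.05), 1 without vascular replicate 2, 4 without littoral replicate 3 and 315 without vascular replicate 3, of which 65 were higher in littoral and 250 higher in vascular cells.

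**Figure D2:**
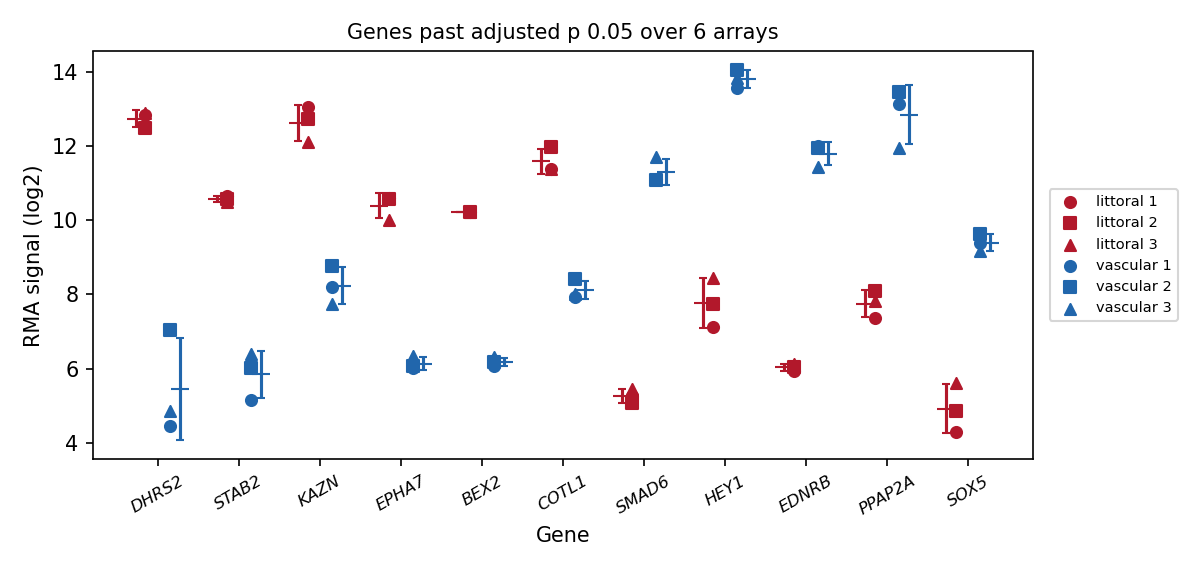
RMA signal (log2) of the 11 genes past adjusted p 0.05, 1 point per array, littoral in red and vascular in blue, with the shape giving the replicate; bars are group means with SD (n = 3). SMAD6 lies at 11.30 ± 0.36 in vascular and 5.26 ± 0.18 in littoral cells.

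Without the replicate 3 arrays, 616 genes were higher in littoral and 730 higher in vascular cells, 1346 in all, among them all 11 of the genes above. With 2 arrays per group left, 1304 of these differed at least 2-fold. The rule for named genes took 15 in each direction by the fitted difference, with the sort antigen CD8A, whose direction the gate fixed, as 1 of the littoral genes. That order was not measured where the dimmer group was at background, and such genes are given as lower bounds. On the littoral side these were the imprinted gene MEST (at least 46.0-fold), NAV3 (at least 35.2-fold), GBA3 (at least 33.6-fold), PRR5L (at least 17.5-fold) and ABCA8 (at least 10.9-fold), with CPB1 also a lower bound. The mannose receptor MRC1 (5.18, SE 0.42) was above background on all 4 arrays. The steroid dehydrogenase HSD17B6, DHRS2, the uncharacterised LOC100506776, the adaptor of B cell receptor signalling BLNK, PCDH7, CNTN3 and the cadherin CDH11 were also higher. Each of these was above background on 1 of 2 vascular arrays, replicate 2. On the vascular side were the semaphorin SEMA3G (at least 68.9-fold), the sialomucin EMCN (at least 64.8-fold), NEDD9 (at least 57.6-fold), TSPAN13 (at least 39.1-fold), the chemokine CXCL12 (at least 38.6-fold), SSUH2 (at least 38.1-fold), NEBL (at least 29.1-fold) and the junction protein JAM2 (at least 27.7-fold). Beside them were PALMD (at least 25.9-fold), EPS8 (at least 21.6-fold), ANK3 (at least 19.2-fold) and LPCAT2 (at least 10.6-fold). HEY1 (-6.36, SE 0.30) was above background on all 4 arrays, and SPARCL1 and TMEM47, also higher in vascular cells, on 1 of 2 littoral arrays. The adjusted p of the genes taken lay between 0.000195 for SEMA3G, EMCN and PALMD and 0.0338 for LOC100506776 (limma). Over 6 arrays with the replicate block, PCDH7 (adjusted p = 0.0247), HSD17B6 and BLNK (both 0.0387), CDH11 (0.0431), CXCL12 and GBA3 (both 0.0445) and the transcription factor FOXC1 (0.0469) also passed. Of the 1346 genes, 1024 (76.1%) kept their direction between the replicate 3 arrays, with a median difference there of 0.73 in that direction.

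**Figure D3:**
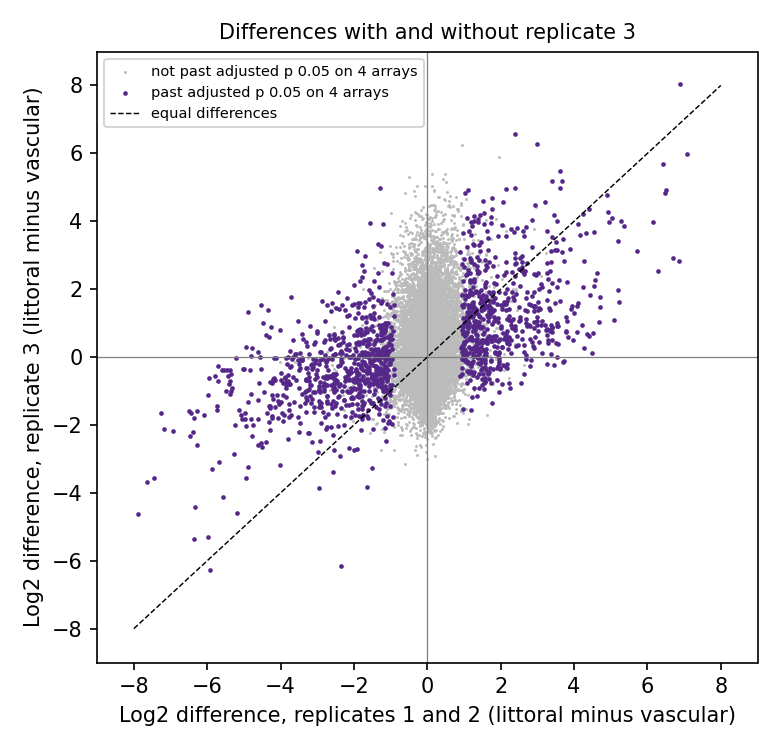
Log2 difference between littoral and vascular cells of each gene on the replicate 1 and 2 arrays (horizontal) and on the replicate 3 arrays (vertical), with the 1346 genes called on the former in purple. Of these, 1024 lie on the same side of 0 on both axes, most of them nearer to 0 on the vertical axis.

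Arterial genes were lower in littoral cells as a group. Of 23 measured members, 22 had a negative difference over 6 arrays, with a median of -1.25, and HEY1 passed the threshold over all genes (8 lower adjusted over the list alone; camera adjusted p = 9.28e-16, and adjusted p = 0.199 with an estimated correlation). Without replicate 3 the median was -1.90, and 13 members were lower and 0 higher (14 and 0 adjusted over the list alone), with SEMA3G, HEY1 and the related repressor HEY2 (at least 15.4-fold) among them. Capillary genes had a median of -1.02 (15 members, 1 higher and 3 lower adjusted over the list alone; camera adjusted p = 4.85e-05, and adjusted p = 0.261 with an estimated correlation). Without replicate 3 the median was -1.70, 9 of these were lower, among them CXCL12, the fatty acid carrier FABP4 (at least 4.83-fold) and TMEM100 (-4.13, SE 0.29), and 2 higher, the integrin ITGA1 (1.68, SE 0.31) and the diaphragm protein PLVAP (1.04, SE 0.21). Basement membrane and matrix genes had a median of -0.75 over 28 members, of which 1 was higher and 4 lower adjusted over the list alone (camera adjusted p = 7.28e-06, and adjusted p = 0.147 with an estimated correlation). Without replicate 3, 10 of them were lower, including fibronectin FN1 (-4.89, SE 0.29), COL8A1 (at least 8.46-fold) and MGP (-3.96, SE 0.51; above background on 1 of 2 littoral arrays), and COL5A1 was higher (at least 3.35-fold); FN1 differed by 1.31, the other way, between the replicate 3 arrays.

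Pan-endothelial genes had a median of -0.46 over 30 members (camera adjusted p = 0.000516, and adjusted p = 0.817 with an estimated correlation). No member passed over 6 arrays (3 lower adjusted over the list alone). Without replicate 3, 11 were lower and 0 higher, among them EMCN, the VEGF receptor KDR (at least 24.6-fold) and the adhesion molecule ESAM (at least 5.42-fold). Among 36 growth factor signalling genes, whose median was -0.35 (camera adjusted p = 0.0376, and adjusted p = 0.391 with an estimated correlation), SMAD6, by the probe set that may cross-hybridise, passed over 6 arrays (4 higher and 3 lower adjusted over the list alone). Without replicate 3, 9 were lower, including KDR and VEGFC (-4.17, SE 0.29), and 5 higher, including ANGPTL2 (3.78, SE 0.22), WNT2 (at least 3.44-fold) and BMP2 (2.16, SE 0.45).

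Venous genes had a median of 0.40 over 14 members, 9 of them positive and 5 negative. The list passed as higher in littoral cells with camera at the preset correlation (adjusted p = 0.0314), but not with an estimated correlation (adjusted p = 0.261). No member passed over 6 arrays (2 higher adjusted over the list alone), and without replicate 3, 6 were higher and 0 lower. They included the apelin receptor APLNR (4.35, SE 0.57), the interleukin receptor IL1R1 (3.48, SE 0.35) and DARC, now ACKR1, a chemokine-binding receptor of venules (2.77, SE 0.39). Lymphatic genes had a median of 0.44 over 16 members (camera adjusted p = 0.00559, and adjusted p = 0.25 with an estimated correlation). STAB2 passed over 6 arrays (4 higher adjusted over the list alone), and without replicate 3 the semaphorin SEMA3D (at least 10.9-fold) and TFF3 (3.23, SE 0.33) were among 5 that were higher. The median was then 0.14 and the camera adjusted p 0.0793, while with the replicate block as well the list passed at the preset correlation. MMRN1 was the 1 lower member (-1.07, SE 0.21), with both group means under the background limits.

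Antigens described on littoral cells had a median of 1.05 over 15 members, 13 of them positive (camera adjusted p = 4.85e-05, and adjusted p = 0.25 with an estimated correlation). STAB2 passed over 6 arrays, and 5 were higher and 1 lower adjusted over the list alone. The list counts SIRPA and FHOD1, which the investigators may have picked from these same samples. The results of those members, and in part that of the list as a whole, are therefore not independent of these data. The list was not tested without them. The signal regulatory protein SIRPA, the receptor for CD47, differed by 1.34 (SE 0.32; adjusted p = 0.318) and the formin FHOD1 by 2.44 (SE 0.53; adjusted p = 0.275). Without replicate 3 the median was 0.75, with 10 members positive and 5 negative. MRC1, STAB2, FHOD1 (3.13, SE 0.20) and SIRPA (1.33, SE 0.28; limma adjusted p = 0.0475) were then among 6 higher members, and endoglin ENG was lower (-1.39, SE 0.22). Scavenger receptors moved in different directions without replicate 3: 5 were higher, including STAB2, MRC1 and OIT3 (3.84, SE 0.54; above background on 1 of 2 vascular arrays), while the lectin FCN3 (at least 25.4-fold), COLEC12 (at least 2.27-fold) and CLEC14A (-2.63, SE 0.28) were lower. The same held for genes of apoptotic and aged cell uptake, with 3 higher, including STAB1 (2.98, SE 0.20), and 5 lower, including GULP1 (at background in littoral cells), MERTK (at least 4.16-fold) and ANXA1 (-3.66, SE 0.54, above background on 1 of 2 littoral arrays). Between the replicate 3 arrays, where these lower genes were under the background limits, GULP1 differed by -1.55, ANXA1 by -0.01 and MERTK by 0.88, the other way.

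**Figure D4:**
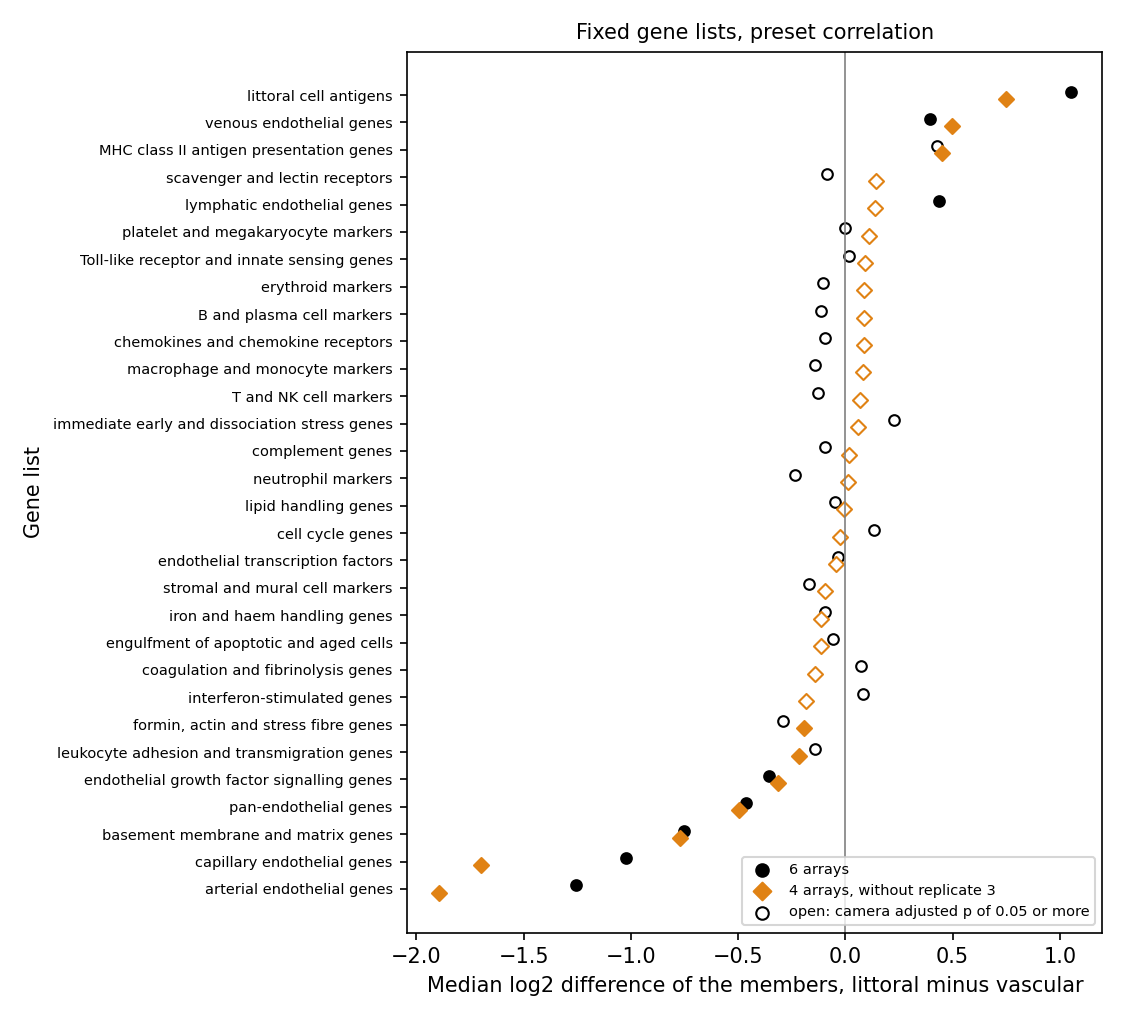
Median log2 difference, littoral minus vascular, of the members of each of the fixed gene lists except the sort antigens, over 6 arrays (black circles) and without replicate 3 (orange diamonds). Filled symbols have a camera adjusted p under 0.05 with the preset correlation; arterial genes lie lowest, with a median of -1.25 over 6 arrays.

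Arterial, capillary and basement membrane genes passed whichever array was left out, with camera at the preset correlation. An estimated correlation, with which 0 lists passed over 6 arrays, was not run with 1 array left out. The adjusted p of the other lists rose past 0.05 without vascular replicate 3 for littoral cell antigens (0.119, median 0.55), lymphatic genes (0.136, median 0.28) and venous genes (0.103, median 0.47), and without littoral replicate 2 for venous genes (0.0516). For pan-endothelial genes it was 0.0874, 0.195 and 0.118, and for growth factor genes 0.256, 0.269 and 0.238, without littoral replicate 3, vascular replicate 1 and vascular replicate 2. Further lists passed with 1 array left out: scavenger receptors (0.036) and MHC class II genes (0.0259), both higher, without littoral replicate 3, and interferon-stimulated genes, lower, without littoral replicate 2 (0.0428). Without vascular replicate 3, interferon-stimulated (0.0221), formin (0.00217), leukocyte adhesion (0.0368) and immediate early genes (0.0368) passed as lower. The median and the camera direction differed in sign over 6 arrays for scavenger receptors (-0.08, up), coagulation genes (0.08, down) and interferon-stimulated genes (0.08, down), and for macrophage, iron, chemokine and transcription factor genes, whose medians were negative and directions up.

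Of the 31 lists, 8 passed with the preset correlation over 6 arrays, 9 with the replicate block and 10 without replicate 3, and 0 passed in any of these fits with an estimated correlation. The replicate block added genes of MHC class II antigen presentation (adjusted p = 0.024, and adjusted p = 0.655 with an estimated correlation). Without replicate 3 this list passed too (adjusted p = 0.00772, and adjusted p = 0.402 with an estimated correlation), where the protease CTSS was higher (1.14, SE 0.20) and the protease LGMN lower (at least 2.59-fold). Formin, actin and stress fibre genes passed without replicate 3 (adjusted p = 0.00772), where 7 of 31 members were lower, among them FMNL2 (at least 4.95-fold), ACTN1 (at least 6.41-fold) and TPM1 (-3.48, SE 0.39), and FHOD1 alone was higher. Leukocyte adhesion genes also passed there (adjusted p = 0.0128), and for both lists the adjusted p was 0.323 with an estimated correlation; among leukocyte adhesion genes, JAM2 and CX3CL1 (at least 3.44-fold) were lower and VCAM1 (2.05, SE 0.39) higher. Among endothelial transcription factors, 4 were higher in littoral cells, including NR2F2 (2.04, SE 0.30) and GATA6 (1.63, SE 0.29), and 6 lower, including FOXC1 (-3.16, SE 0.27; above background on 1 of 2 littoral arrays) and SOX17 (-1.90, SE 0.23); the list as a whole did not pass.

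The remaining lists did not pass in these fits, while single members did without replicate 3. Among coagulation genes 4 were lower and 2 higher. The lower were F2RL1 (at least 2.56-fold), ENTPD1 (-1.87, SE 0.28), the plasminogen activator PLAT (at background in littoral cells and on 1 of 2 vascular arrays) and MMRN1, and the higher the tissue factor inhibitor TFPI (1.68, SE 0.19) and the protein C receptor PROCR (1.62, SE 0.27). Among complement genes the receptor CD93 (-5.09, SE 0.25) and CD59 (-1.67, SE 0.25) were lower and CFI (1.73, SE 0.19) higher. The iron exporter SLC40A1 (1.93, SE 0.36) and the TLR4 partner LY96 (1.42, SE 0.19) were higher in littoral cells. Of chemokines and their receptors 4 were higher, among them DARC, CCL23 (3.09, SE 0.27; above background on 1 of 2 vascular arrays) and CXCL11 (at least 2.04-fold). The 3 lower were CXCL12, CX3CL1 and the receptor CXCR4 (-2.37, SE 0.22). IFITM1 (-2.15, SE 0.28) and ISG15 (-1.51, SE 0.29) were lower. Of immediate early and stress genes 3 were lower, among them EGR3 (at least 7.40-fold) and MYC (-2.33, SE 0.28), and HSPH1 was higher (2.39, SE 0.38). No cell cycle gene passed in either fit, and among lipid handling genes 3 were higher and 2 lower, the latter FABP4 and GPIHBP1 (-3.20, SE 0.50).

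Markers of T, B, myeloid, erythroid, platelet and stromal cells did not pass as lists over 6 arrays, with the replicate block or without replicate 3; stromal markers passed, lower in littoral cells, without littoral replicate 3 (adjusted p = 0.00774) and without vascular replicate 1 (adjusted p = 0.0114). Of 20 T and NK cell markers, 15 were at background on every array, as were 12 of 18 B and plasma cell markers, 12 of 22 macrophage and monocyte markers and 11 of 14 erythroid markers. So were 9 of 13 neutrophil and 9 of 11 platelet and megakaryocyte markers. Of 20 stromal and mural markers, 8 were at background on every array and 3 above it on all 6. The single member of these lists past the threshold without replicate 3 was LTF, listed as a neutrophil marker, at 3.97 (SE 0.23, limma adjusted p = 0.000708). It was above background on 1 of 2 vascular arrays. CD14 differed by 0.54 over 6 arrays (adjusted p = 1).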

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

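Of the tests in this part, the splits of the samples were planned, and those on the replicate 3 arrays, the vascular replicate 2 array and the B cell receptor genes were chosen after the results were seen. Probe sets with several gene symbols were left out of the comparison of genes, and a signal above background on all 6 arrays was seen in a pair of those that hold members of the fixed lists. The HLA-DRB1 probe set, which also names a pair of uncharacterised genes, had a mean of 11.3, at 11.52 ± 2.61 in littoral and 11.11 ± 2.27 in vascular cells (SD, n = 3). The probe set shared by HSPA1A and HSPA1B had a mean of 13.9, at 14.33 ± 0.09 and 13.40 ± 1.31 (SD, n = 3).

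The genes called without replicate 3 differed less between the replicate 3 arrays than between the other arrays, by a median of 0.73 against 1.93 in the direction of the call. They were chosen by their differences on those other arrays, so part of this drop follows from the choice. How large that part is was not measured. Vascular replicate 3 was least like its group, and over all probe sets the replicate 3 arrays were less alike than the other same-numbered pairs (Pearson's r 0.815 against 0.934 and 0.939). Exchanged labels of the replicate 3 arrays are argued against by 76.1% of the 1346 genes called without them keeping their direction there, and a mere change of scale by the rank correlation of vascular replicates 1 and 3, 0.703 against 0.981 for replicates 1 and 2. On vascular replicate 3, 794 genes bright and flat on the other arrays lay lower by a median of -3.05 (quartiles -4.39 and -1.62), and on littoral replicate 3 by -1.37, while 771 genes picked the same way gave 0.00 on vascular replicate 2. Lower signal over background may therefore account for part of the pattern. A batch, a sample from outside the study, another mix of cells and a biological difference between donors stay open, untested.

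Genes high in littoral cells lay higher on vascular replicate 2 than on vascular replicate 1: 28 of 30 such genes did, with a median shift of 1.04. A shift of the whole array is argued against by 232 flat genes equally bright on littoral replicates 1 and 2, whose median shift was 0.0311. The probe sets of the background limit shifted by a median of -0.01. The flat genes were not matched to the 30 genes in brightness on the vascular arrays, so a shift at the level of the 30 genes alone was not tested. Littoral cells carried into the sorted vascular sample may account for it, at a median of 2.19% of the littoral signal (quartiles 1.37% and 4.16%). In the mirror case, 14 of 31 vascular genes lay higher on littoral replicate 2 than on replicate 1, with a median shift of -0.09. A low expression of these genes by vascular cells of that sample stays open.

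BLNK was higher in littoral cells without replicate 3, where 1 of 2 vascular arrays was above background, and other adaptors and kinases of B cell receptor signalling, named after their values were seen, lay high too: PIK3AP1 at least 15.9-fold, VAV3 at 3.27 and LYN at 3.20, while PLCG2 lay at -3.84. B cells among the littoral cells, which the CD45 gate would remove, are argued against by the B and plasma cell markers, of which 1 of 18 was at least 1 log2 unit higher in littoral cells. Whether the pathway as a whole shifts cannot be told apart from no shift, since camera's adjusted p for its 23 genes was 0.295 (0.197 before adjustment), with members going both ways. Littoral cells may express these genes themselves, a hypothesis for which no further test was run.

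The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. The real split alone, 1 of 10, gave as many differing genes (11, highest other 0), genes higher in littoral cells (6, highest other 0), genes higher in vascular cells (5, highest other 0) and genes differing at least 2-fold (11, highest other 0). For the gene lists, 4 of 10 splits moved 8 or more lists, with 8 in the real split and 14 in the highest other, which set littoral replicates 1 and 3 with vascular replicate 3 against the rest. Among the splits that part all 3 same-numbered pairs of arrays, the others moved 10, 2 and 0 lists.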

How the results depend on the processing

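The fits without both replicate 3 arrays, with the two-level block and with array weights were chosen after the results were seen; the other alternatives were planned. Signal over background limits the data: 7355 genes were at background on all 6 arrays, and leaving out any 1 array moved the call counts, from 11 to between 0 and 315 (higher in littoral cells 0 to 65, higher in vascular cells 0 to 250, at least 2-fold 0 to 315). The direction of all 11 genes held under each alternative that fits 1 value per gene, except for SMAD6 when cross-hybridising probe sets were left out (0.15), as the 1 probe set left lay under the background limits. With arrays left out, a block, a filter, weights or another test on the same values, the direction could not change. The arrays of the groups did not overlap for these genes. Where not stated otherwise, the cause of a change was not tested. The analysis of the annotated table in place of the series table was not run.

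The replicate block gave 55 genes, 43 higher in littoral and 12 in vascular cells, 55 at least 2-fold, and an adjusted p of 0.024 for MHC class II genes; it changed no other list call of camera at the preset correlation. Without both replicate 3 arrays there were 1346, 616, 730 and 1304 genes, and the adjusted p was 0.0793 for lymphatic endothelial genes, 0.00772 for formin, actin and stress fibre genes and for MHC class II genes and 0.0128 for leukocyte adhesion genes. With the replicate block as well there were 2513, 1260, 1253 and 1889 genes, with 0.00162, 0.00162 and 0.0103 for formin, MHC class II and leukocyte adhesion genes. A two-level block of replicate 3 against the rest gave 275, 170, 105 and 275 genes and 0.0442 for MHC class II genes. Array weights gave 1612, 784, 828 and 1443 genes, with 0.00985, 0.00886 and 0.0102 for formin, MHC class II and leukocyte adhesion genes.

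Quantile normalization again gave 45, 23, 22 and 45 genes and 0.0674 for growth factor genes. Median centring gave 6, 3, 3 and 6 genes, 0.102 for venous and 0.0534 for growth factor genes. The filter on the mean and that on background each gave 6, 3, 3 and 6 genes, the latter with 0.291 for growth factor genes. The mean of probe sets gave 2, 1, 1 and 2 genes and 0.0337 for formin genes, and each probe set on its own 18, 10, 8 and 18. Without cross-hybridising probe sets 2 genes were higher in vascular cells, and the adjusted p was 0.201 for venous, 0.00206 for leukocyte adhesion and 0.814 for growth factor genes. The Welch test called 0, 0, 0 and 0 genes, with 761 at an unadjusted p under 0.05 against 1140 with limma, and treat 5, 2, 3 and 5. An intensity trend with robust eBayes gave 12 genes, 7 higher in littoral and 5 in vascular cells, and 8 of the 11 genes stayed past the threshold. The share of calls higher in littoral cells was 54.5% over 6 arrays, 51.1% after quantile normalization and 50% after median centring, but 78.2% with the replicate block, 77.8% without cross-hybridising probe sets (7 of 9), 40% with treat and 20.6% without vascular replicate 3.

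With an estimated correlation 0 lists passed, at 0.25 for littoral cell antigens, 0.817 for pan-endothelial, 0.1995 for arterial, 0.261 for venous, 0.261 for capillary, 0.25 for lymphatic, 0.147 for basement membrane and 0.391 for growth factor genes. With fry 2 lists passed over 6 arrays, lymphatic genes at 0.0125 and basement membrane genes at 0.0487. With the replicate block 0 passed, these at 0.074 and 0.15, and without both replicate 3 arrays 9 passed. The adjusted p with fry over 6 arrays was 0.113 for littoral cell antigens, 0.756 for pan-endothelial, 0.0572 for arterial, 0.0572 for venous, 0.17 for capillary and 0.17 for growth factor genes.

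With 1 array left out, the adjusted p ran from 0.00728 to 0.103 for venous, 1.18e-12 to 0.195 for pan-endothelial, 0.00024 to 0.269 for growth factor, 9.86e-06 to 0.119 for littoral antigen and 0.00227 to 0.136 for lymphatic genes. It ran from 0.0221 to 0.871 for interferon-stimulated, 0.036 to 0.703 for scavenger receptor, 0.00774 to 0.949 for stromal, 0.0259 to 0.374 for MHC class II, 0.00217 to 0.657 for formin and 0.0368 to 0.771 for leukocyte adhesion genes. For immediate early genes it ran from 0.0368 to 0.921, the former without vascular replicate 3, where the list lay lower in littoral cells and the direction was reversed. Of 127 named genes, 120 kept their side of the threshold with the replicate block and 7 passed it.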

Other observations

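The lists in this part and their tests were chosen after the results were seen. Heat shock proteins and co-chaperones lay higher in littoral cells, with 20 of 25 members positive and a median of 0.80 over 6 arrays (camera adjusted p = 7.89e-05 over the added lists), though the adjusted p was 0.348 with an estimated correlation and 0 members passed on their own. Without replicate 3 the median was 0.44, and 5 members were higher, the small heat shock protein HSPB8 by 4.52 (SE 0.45; above background on 1 of 2 vascular arrays), HSPH1 by 2.39 (SE 0.38), CHORDC1 by 1.42 (SE 0.27), the mitochondrial chaperonin HSPD1 by 1.20 (SE 0.22) and DNAJA1 by 1.17 (SE 0.23), and 0 lower (limma; camera adjusted p = 0.000195, and adjusted p = 0.2 with an estimated correlation). Of the list, 3 members are also in the fixed list of dissociation stress genes. The cells had been freed by enzymes and sorted, and no test here sets that apart from a difference between the cell types.

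Axon guidance ligands and receptors went both ways. Of 66 members, 9 were higher and 6 lower in littoral cells without replicate 3 (camera adjusted p = 0.995), with the ephrin receptor EPHA7 (at least 15.9-fold), the semaphorins SEMA3D (at least 10.9-fold) and SEMA3A (at least 2.28-fold), SLIT2 (15.3-fold) and its receptor ROBO1 (5.85-fold) on the littoral side and SEMA3G (at least 68.9-fold) and EPHA3 (at least 1.59-fold) on the vascular side. The list as a whole was thus not shifted by this test, over 6 arrays either (camera adjusted p = 0.489).

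Among probe sets with several symbols, those of GJA5, a connexin of arterial endothelium, and FABP5 averaged 9.64 ± 2.72 and 9.19 ± 2.05 in vascular cells (SD, n = 3), above background on 2 of 3 arrays, and were at background on all littoral arrays. CCL14 differed by 3.26 and FLRT2 by 2.57 over 6 arrays, both above background on 5. Each of these had an adjusted p of 0.298 or more (limma, over probe sets). Of 9513 probe sets with no symbol, 1 passed over 6 arrays, higher in littoral cells, with 391 at an unadjusted p under 0.05, and 187 passed without replicate 3.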
